A study of Mus musculus with 5 samples.

How the data were processed

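RNA-seq gene counts were analysed for 5 libraries labelled as sorted tumour-associated macrophages from mouse EO771 tumours, 2 from Treg-ablated and 3 from untreated control tumours. Groups and replicate numbers were taken from the sample titles. The file names carry other numbers for the Treg-ablated libraries, 2 for replicate 1 and 3 for replicate 2 of the titles, while those of the controls match, so a replicate number here means that of the title only. Per the file headers, the authors made the deposited counts with featureCounts 1.6.2, which counted fragments over exons and summed them per gene, on a filtered Ensembl 83 annotation of GRCm38. The values are whole-number counts that are not normalized. The submitters' processing notes also name FastQC 0.11.5, Trimmomatic 0.33, Subread 1.6.2 and DESeq2 1.16.1. The recorded command sets no strand option, although the labels describe a stranded library kit, so reads of a gene and of an overlapping or antisense neighbour cannot be told apart. It sets no option for reads with several best matches, so genes with near-identical copies (class I MHC, immunoglobulin, ribosomal protein and other genes with pseudogenes) have uncertain values. Gapdh, for example, which has many processed pseudogenes, had 30.88 ± 2.533 CPM in controls. Whether shared reads lowered this value was not tested.

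Each file lists 46983 genes, of which 21043 had 0 counts in every library. Symbols were joined by Ensembl identifier and found for 46488 genes. The 37 mitochondrially encoded genes had 0 counts in all libraries, so the mitochondrial list could not be tested and the mitochondrial share says nothing about RNA quality here. Library totals ran from 13122668 to 20156835 counts. Replicates of a group differed beyond sampling noise, with a chi-square per degree of freedom between 4.192 and 7.896, so none was treated as a duplicate. A count of 3 in the tested genes corresponds to between 0.1502 and 0.2263 CPM per library. Intervals and floors cover counting error only.

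Genes were kept by filterByExpr (14580 genes), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, Treg-ablated against control without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. SEs of log2 fold changes were taken as the log2 fold change divided by the square root of F. CPM are counts divided by the TMM-scaled library size and multiplied by 1e+06. Gene lists, 38 in all, were fixed before the data were examined, together with the test, the rule for named genes and the alternatives other than the GC correction. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for the 37 lists with at least 5 genes tested. Counts of members are given over all genes and adjusted over the list alone. Many lists share genes, so they are not independent results. Of the 28 listed classical activation genes 14 are also in other lists, as are 11 of the 38 IFN-γ response genes. With 3 residual degrees of freedom the estimated correlation is itself imprecise.

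Named genes are the 12 higher and 12 lower with the largest change among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3, groups that do not overlap and a symbol that is not a predicted gene or pseudogene. To these were added up to 4 members per list with the smallest p and a fixed set of markers. Other genes are named as chosen after their values were seen. Gene positions are those in the files (GRCm38).

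Alternatives were RLE size factors, library size alone, 2 other low-count filters, DESeq2 1.42.0, limma-voom, a test against a fold of 1.5, the replicate number as a block, thinning to the smallest library, an offset on gene length and leaving out each library in turn. Leaving out a Treg-ablated library leaves 1 in that group, which is then assumed to vary like the controls. For lists they were an estimated correlation, fry and a prior count of 0.5 in place of the other tests. A per-library lowess offset on GC content, taken from GENCODE M21 transcripts, was added after seeing the data. The gene test was checked on simulated counts drawn from the real means, library sizes and dispersions, over 14350 genes tested. The 200 changed genes, far fewer than were called in the data, were taken from those with a mean of at least 1 CPM. Recovery of lower genes is therefore not covered. The test recovered 74.6% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold. It also called 15 unchanged genes, 7.94% of its calls, more than the threshold of 0.05 aims at. In a second simulation with a GC trend, over 14363 genes, 347 unchanged genes were called without the offset and 14 with it. These were 66.1% and 7.29% of the calls. Camera called the 1 simulated list raised 1.5-fold and 0 of 30 unchanged lists. The simulated genes were drawn independently of each other, so this check does not cover correlation between the genes of a list. Exact intervals used scipy 1.17.1 and plots matplotlib 3.10.9.
Some results of the named-gene rule are not reported here.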

Results

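The study used mice bearing EO771 tumours, a mouse mammary carcinoma line grown in the mammary gland. Regulatory T (Treg) cells were depleted with 2 doses of diphtheria toxin at 50 µg per kg, and cells were sorted on day 4. RNA from the sorted cells was sequenced. Per the labels the sorted cells were tumour-associated macrophages (CD45+ CD11b+ Ly6G− F4/80+). There were 2 libraries from Treg-ablated tumours and 3 from untreated controls, which allowed 1 comparison. As the controls were untreated, an effect of the toxin itself cannot be told apart from one of Treg loss. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Totals were 15789199 and 13122668 counts in Treg-ablated replicates 1 and 2, and 14893625, 20156835 and 14520524 in control replicates 1, 2 and 3. Values below are CPM (counts scaled by library size) as mean ± SD, with n = 2 for Treg-ablated and n = 3 for control libraries.

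Fibroblast markers lay far above the mature macrophage genes in all 5 libraries. The median CPM of 22 fibroblast markers lay between 99.17 and 121.2 per library, whereas that of 23 mature macrophage genes lay between 6.185 and 9.866. Fn1, which encodes fibronectin, had 7850 to 11750 CPM and Col3a1, a fibrillar collagen, 7467 to 9556 CPM. The genes behind the sort gate were low by comparison. Ptprc, which encodes CD45, ranged from 22.08 to 32.96 CPM, Itgam, which encodes CD11b, from 12.22 to 19.01 CPM, and Adgre1, which encodes F4/80, from 5.733 to 9.866 CPM. Other myeloid transcripts were not all low: Lyz2, the lysozyme gene, had 99.04 to 204.6 CPM. Per kilobase of exon Lyz2 had 78.23 to 161.6 CPM against 70.71 to 115.9 for the collagen gene Col1a1. Col3a1 and Fn1 were far higher per kilobase, at 760.7 to 973.5 and 671.8 to 1006 CPM. Ly6g, which the gate excluded, was at most 0.1891 CPM. Median CPM per library did not exceed 0.626 for 18 neutrophil markers or 0.6304 for 21 epithelial and mammary tumour markers. Of the latter list, however, the keratin genes Krt18 and Krt8 had 179.6 to 222.4 and 74.75 to 89.84 CPM. Fn1, Col3a1, Krt18 and Krt8 were singled out after their values were seen. The libraries are therefore called "labelled as sorted macrophages" below, and changes are described without assigning them to a cell type.

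**Figure D1:**
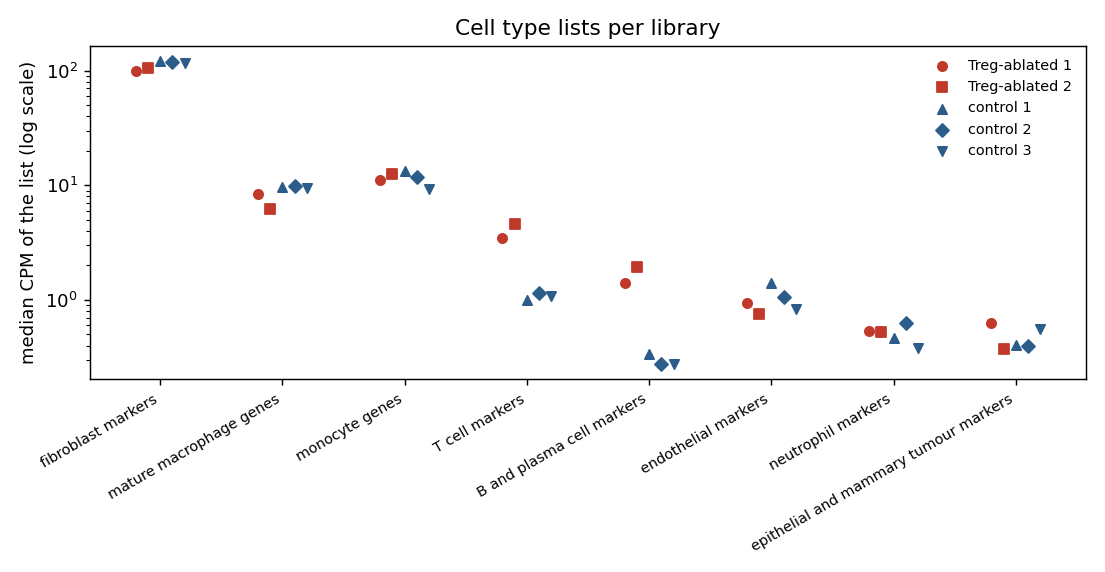
Median CPM (log axis) of the genes of 8 cell type lists in each library; red symbols are the 2 Treg-ablated and blue symbols the 3 control libraries. Fibroblast markers lie near 100 CPM in every library, and the T cell and B cell medians are higher in both Treg-ablated libraries than in any control.

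Foxp3, the transcription factor that defines Treg cells, was too low to serve as a check of the ablation. It had 1 and 5 counts in the Treg-ablated libraries and 3, 9 and 3 counts in the controls. Summed counts were divided by the summed library totals of each group. The ratio of these values, Treg-ablated to control, was 0.686 with an exact 95% interval of 0.218 to 1.871, which covers counting error only. A difference was not detectable at this depth.

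The comparison asked how the transcripts of these tumour-derived cells differed after Treg ablation, in a study concerned with IFN-γ made by CD4+ T cells. Most of the listed genes induced by IFN-γ and of T, NK and B cells, and some MHC class I genes, were higher after ablation. Many genes of cholesterol synthesis and several mature macrophage and fibroblast genes, the collagen genes Col1a1 and Col6a2 among them, were lower. Of 14580 genes tested with edgeR, 1971 were higher and 1787 lower at an adjusted p under 0.05. Most changes were small: 2822 of the called genes changed by less than 1.5-fold, and 305 were higher and 99 lower by more than 2-fold. Tested against a fold of 1.5, 98 genes were higher and 23 lower. Without control replicate 2 the counts were 812 and 554, and DESeq2 called 1214 genes higher. With a correction for GC content chosen after seeing the data, 59.18% of the 3758 calls of the main fit were kept in the same direction.

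Most IFN-γ response genes rose. Of 38 members, 32 were higher, 1 was lower and 5 did not pass, with the same numbers when adjusted over the list alone, and the median log2 fold change was 1.11. The set test (camera) gave an adjusted p of 4.889e-17 with the preset correlation, and an adjusted p of 0.0719 with an estimated correlation. The chemokine gene Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889, GRCm38) rose from 47.99 ± 2.417 to 156.6 ± 10.15 CPM, a log2 fold change of 1.71 (SE 0.0736, adjusted p = 1.351e-06). Its neighbour Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), which like Cxcl10 attracts T cells, rose from 29.56 ± 0.2292 to 90.14 ± 7.684 CPM (log2 fold change 1.61, SE 0.0759, adjusted p = 2.053e-06). The guanylate-binding protein genes Gbp4 and Gbp2 rose 3.62-fold and 2.3-fold. Irf1, a transcription factor of the interferon response, rose 1.67-fold. Cd274, which encodes the inhibitory ligand PD-L1, went from 23.04 ± 2.326 to 64.47 ± 6.748 CPM (log2 fold change 1.48, SE 0.0982, adjusted p = 1.545e-05). Nos2, the inducible nitric oxide synthase, rose 2.34-fold. Ciita, the activator of MHC class II genes, was among the members that did not pass (log2 fold change −0.12, SE 0.1166, adjusted p = 0.4999). Fcgr1, an Fc receptor gene, fell 2.21-fold. Tested against a fold of 1.5, 23 members were higher.

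Ifng itself was low. It rose from 0.7978 ± 0.04303 to 3.098 ± 0.4338 CPM (log2 fold change 1.96, SE 0.2513, adjusted p = 0.000791). The receptor gene Ifngr1 was 1.18-fold higher (adjusted p = 0.0239), a call that ended without Treg-ablated replicate 2, without control replicate 2, and with a correction for GC content chosen after seeing the data (adjusted p = 0.0902, 0.1259 and 0.05399). Ifngr2 did not pass (log2 fold change 0.06, SE 0.0787).

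Some MHC class I genes rose, while no MHC class II gene passed as higher. In the class I list 11 of 21 members were higher, 10 did not pass, and 12 were higher when adjusted over the list alone. Camera gave an adjusted p of 9.798e-05, and the adjusted p was 0.4368 with an estimated correlation. B2m, the invariant light chain, rose from 1147 ± 64.94 to 1858 ± 139.7 CPM (log2 fold change 0.70, SE 0.0794, adjusted p = 0.000449). H2-Q6 rose 1.88-fold and H2-K1 1.24-fold; these genes have close paralogs, so their values are uncertain where reads were shared. Without Treg-ablated replicate 1, and likewise without control replicate 2, 6 members were higher, and H2-K1 no longer passed (adjusted p = 0.08098 and 0.06649). In the class II list 1 of 13 members was lower and 12 did not pass, and the call ended when adjusted over the list alone (camera adjusted p = 0.1176). This list depended on the processing: without Treg-ablated replicate 1 camera called it lower (adjusted p = 0.000742) with 5 members lower, the filter on 1 count in any library gave an adjusted p of 0.0391 with 3 members lower, and the gene length offset gave 6 lower. The member that fell was Ctss, a lysosomal protease gene (log2 fold change −0.30, SE 0.0944, adjusted p = 0.0386). It did not pass when scaled by library size alone (log2 fold change −0.28), or without Treg-ablated replicate 2, control replicate 1 or control replicate 2. H2-Ab1 and Cd74 had log2 fold changes of −0.25 (SE 0.1177) and −0.16 (SE 0.0849) and did not pass, but both passed as lower without Treg-ablated replicate 1 (log2 fold changes −0.49 and −0.30) and with the gene length offset.

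**Figure D2:**
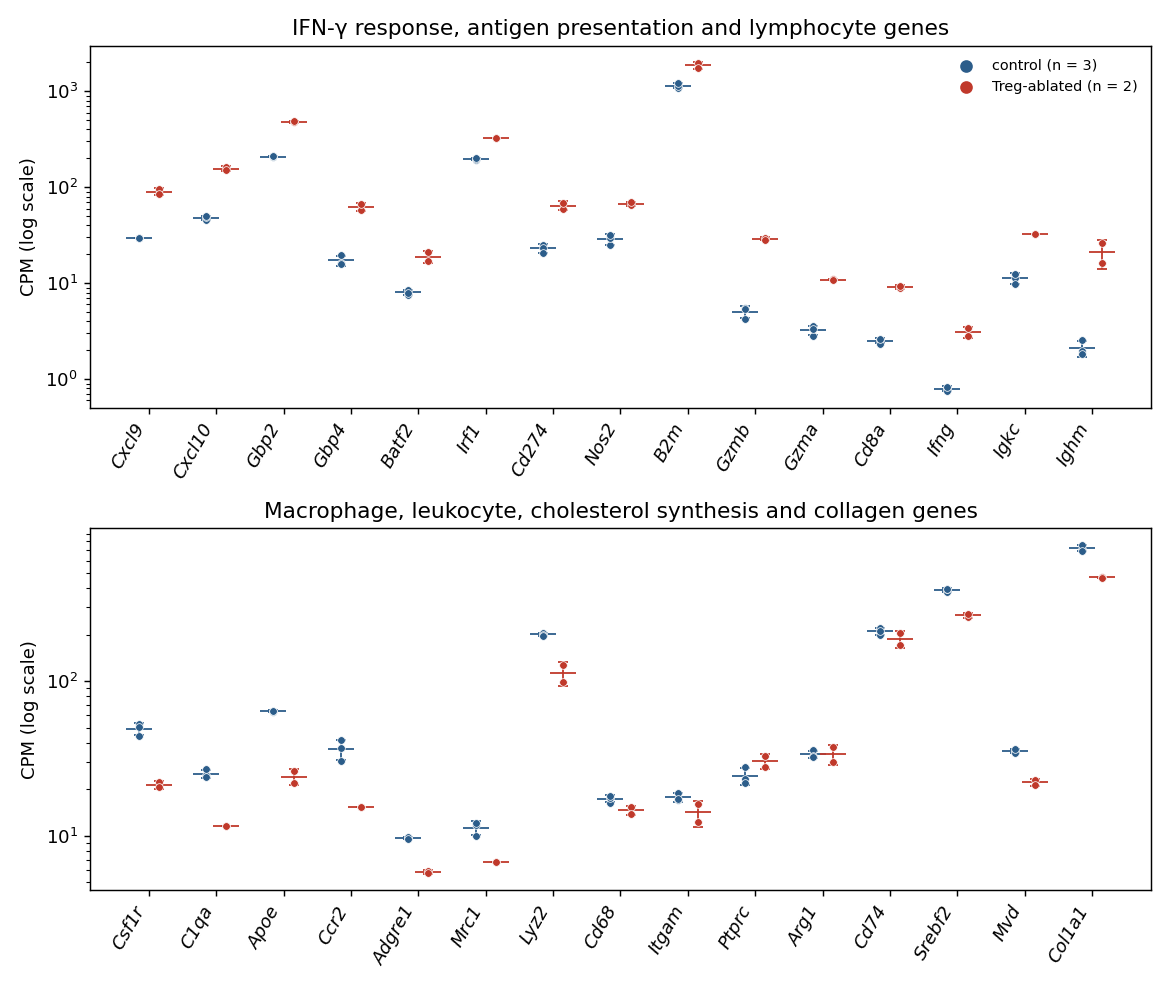
CPM (log axis) of 30 genes in each library; points are libraries, horizontal bars the group means and whiskers the SD, in blue for 3 control and red for 2 Treg-ablated libraries. Cxcl10 lies near 157 CPM after ablation and 48 CPM in controls, Gzmb near 29 and 5.1 CPM, and Csf1r near 21 and 49 CPM, while the groups overlap for Arg1 and Cd74.

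Most listed genes of T cells, cytotoxic cells and B cells were higher after ablation, from low levels. Of 21 T cell markers tested, 19 were higher and 2 did not pass (21 higher adjusted over the list alone). Of 17 cytotoxic T and NK cell markers 14 were higher (14 adjusted over the list alone), and of 12 B and plasma cell markers 10 were higher (12 adjusted over the list alone). Median log2 fold changes were 1.55, 1.32 and 2.40. Camera gave adjusted p of 2.896e-14, 2.665e-10 and 7.546e-09, and with an estimated correlation the adjusted p were 0.1955, 0.1025 and 0.1955. Gzmb, which encodes the cytotoxic protease granzyme B (ENSMUSG00000015437, chromosome 14, 56258856 to 56262260), rose from 5.058 ± 0.7163 to 29.03 ± 0.9418 CPM (log2 fold change 2.51, SE 0.1206, adjusted p = 2.053e-06). Cd8a, a marker of cytotoxic T cells, rose 3.63-fold to 9.128 ± 0.4261 CPM, and the T cell kinase gene Lck 3.29-fold. Cd4 had 1.473 ± 0.05648 against 0.7322 ± 0.3202 CPM and did not pass (adjusted p = 0.0782). It passed without control replicate 2, where its log2 fold change was 1.42, and with the filter on 1 count in any library (0.92). The immunoglobulin genes Igkc and Ighm rose 2.89-fold to 32.45 ± 0.1209 CPM and 9.81-fold to 21.27 ± 7.256 CPM. Ms4a1, which encodes CD20 and was chosen after its values were seen, had 34 counts over the Treg-ablated libraries and 0 over the controls, so it was at least 19.1-fold higher against a floor of 3 counts over the control group. DESeq2 called 8 of the cytotoxic and 3 of the B cell markers higher. In the Treg marker list, which includes genes of activated T cells in general, 5 of 8 members tested were higher (6 adjusted over the list alone; camera adjusted p = 0.00184, and adjusted p = 0.1955 with an estimated correlation). The members higher were Il2ra, Ctla4, Ikzf2, Tnfrsf9 and Icos. Of these, Icos and Ctla4, receptors that activated T cells also carry, rose 4.11-fold and 3.54-fold.

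Many mature macrophage and complement genes fell. Of the genes behind the gate, Adgre1 passed as lower and Itgam and Ptprc did not pass. Of 20 mature macrophage genes tested 9 were lower, 1 was higher and 10 did not pass (9 lower and 2 higher adjusted over the list alone), with a median log2 fold change of −0.33, a camera adjusted p of 0.000133, and an adjusted p of 0.1825 with an estimated correlation. Csf1r, the receptor for the macrophage growth factor CSF-1 (ENSMUSG00000024621, chromosome 18, 61105572 to 61132149), fell from 48.96 ± 4.314 to 21.42 ± 1.273 CPM (log2 fold change −1.19, SE 0.0973, adjusted p = 6.789e-05). C1qa, a subunit of complement C1q, fell 2.18-fold, Apoe, the apolipoprotein E gene, 2.64-fold, and Adgre1 1.67-fold (adjusted p = 0.00275). Mrc1, which encodes the mannose receptor CD206, fell 1.67-fold. Cd68 and Itgam had log2 fold changes of −0.24 (SE 0.1039) and −0.32 (SE 0.1271) and did not pass, while Ptprc was at 0.32 (SE 0.1146), also without passing. Itgam and Ptprc, but not Cd68, passed with the filter on 1 count in any library. Itgam passed as lower and Ptprc as higher without Treg-ablated replicate 1 (log2 fold changes −0.54 and 0.43), and Ptprc also without control replicate 1 (0.42). The only mature macrophage gene that was higher was Vcam1, an adhesion molecule that other cells also make (log2 fold change 0.23), chosen after its value was seen; 0 members were higher without Treg-ablated replicate 2, control replicate 2 or control replicate 3, and 2 without control replicate 1.

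Among 19 monocyte genes 7 were lower and 3 higher (8 and 3 adjusted over the list alone). Camera gave an adjusted p of 0.0215, with an adjusted p of 0.3052 under an estimated correlation, and the call ended without Treg-ablated replicate 2. Ccr2, the chemokine receptor of inflammatory monocytes, fell 2.35-fold, F13a1, a coagulation factor gene, 2.74-fold and Lyz2, the lysozyme gene, 1.77-fold. Ly6c2, another monocyte gene, was 1.46-fold higher (adjusted p = 0.0332), and this call ended under DESeq2, after thinning and without any of Treg-ablated replicate 1, control replicate 2 or control replicate 3. Of 22 Fc receptor and complement genes 9 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.000186, and adjusted p = 0.3052 with an estimated correlation), and 0 were higher without Treg-ablated replicate 2 or control replicate 2. C1qa, C1qb and C1qc are among these lower genes and also among the lower mature macrophage genes. The alternative activation list went both ways, with 8 higher and 8 lower of 27 (9 and 9 adjusted over the list alone, camera adjusted p = 0.4908). Without Treg-ablated replicate 1, 6 were higher and 5 lower, and without control replicate 2 the numbers were 4 and 5. Arg1, which encodes arginase and is a common marker of that state, had 33.78 ± 5.1 against 33.6 ± 1.923 CPM (adjusted p = 0.9374). Of 21 lipid-associated macrophage genes 3 were higher and 4 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.3814), among them Spp1, which encodes osteopontin and rose 1.42-fold, and 1 was higher without Treg-ablated replicate 1 or control replicate 2.

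Most cholesterol synthesis genes tested fell. Of 23 members 16 were lower and 7 did not pass (17 lower adjusted over the list alone), with a median log2 fold change of −0.31, a camera adjusted p of 1.226e-07, and an adjusted p of 0.1025 with an estimated correlation. Srebf2, which encodes a transcription factor that drives the pathway, fell from 388.7 ± 9.493 to 265.9 ± 10.08 CPM (log2 fold change −0.55, SE 0.0663, adjusted p = 0.000604). Mvd, which encodes an enzyme of the mevalonate pathway, fell 1.59-fold. Without control replicate 2, 8 members were lower. Tested against a fold of 1.5, 0 members were lower, and with the correction for GC content 15 were. Of 33 lysosome genes 11 were lower and 2 higher (17 and 3 adjusted over the list alone; camera adjusted p = 0.00116, and adjusted p = 0.3507 with an estimated correlation). Lower and higher members numbered 4 and 0 without control replicate 2, and 6 and 1 without Treg-ablated replicate 2. None was higher without Treg-ablated replicate 1 or control replicate 1, and 17 were lower with the gene length offset.

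Fibroblast markers were lower in 11 and higher in 2 of 22 genes (15 and 3 adjusted over the list alone), with a camera adjusted p of 0.00116 and an adjusted p of 0.1955 with an estimated correlation. The numbers were 7 and 1 without control replicate 2. The collagen genes Col1a1 and Col6a2 fell 1.55-fold and 1.6-fold, and Postn, which encodes the matrix protein periostin, 1.53-fold. Col3a1 did not pass (log2 fold change 0.04, SE 0.1092). Svep1, which encodes an extracellular matrix protein, fell from 13.05 ± 1.12 to 4.651 ± 0.7827 CPM, with a log2 fold change of −1.50 (SE 0.1492, adjusted p = 0.000233). The fibroblast and macrophage lists were both lower in the libraries in which the lymphocyte lists were higher.

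Some inflammatory and chemokine genes rose. Of 22 genes of classical activation and inflammatory cytokines 12 were higher and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 0.000262, and adjusted p = 0.1955 with an estimated correlation). Without control replicate 2, 5 were higher, and without Treg-ablated replicate 2, 8 were higher; neither of these fits nor that without control replicate 1 called a member lower. Of 10 chemokines that attract T cells 7 were higher (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.781e-05, and adjusted p = 0.3052 with an estimated correlation), although 9 of the 13 listed genes also belong to other lists. Chemokines that attract myeloid cells were higher in 9 and lower in 2 of 16 genes (9 and 2 adjusted over the list alone). Camera gave an adjusted p of 0.0334 for them and an adjusted p of 0.5926 with an estimated correlation, and the call ended under 5 other alternatives, which included leaving out Treg-ablated replicate 1. Without that library or control replicate 2, 5 were higher, and without Treg-ablated replicate 2 or control replicate 2, 1 was lower. Cxcl1, which attracts neutrophils, rose 1.53-fold to 650.8 ± 46.23 CPM and Ccl2, which attracts monocytes, 1.6-fold to 586.8 ± 57.09 CPM.

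Of 28 genes of the dissociation and stress list, which holds genes that tissue dissociation can induce, 13 were higher in the same libraries and 1 was lower (16 and 2 adjusted over the list alone; camera adjusted p = 0.000409, and adjusted p = 0.2697 with an estimated correlation). The number lower was 2 without Treg-ablated replicate 2 and 0 without any other library. Jun rose 1.37-fold and Nfkbia, an inhibitor of NF-κB that is itself induced by it, 1.63-fold. Fold changes also followed GC content. Across 9335 protein-coding genes Spearman's rho between the log2 fold change and GC content was −0.44, with genes not being independent replicates, and the median log2 fold change went from 0.14 in the tenth of genes lowest in GC to −0.16 in the highest.

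**Figure D3:**
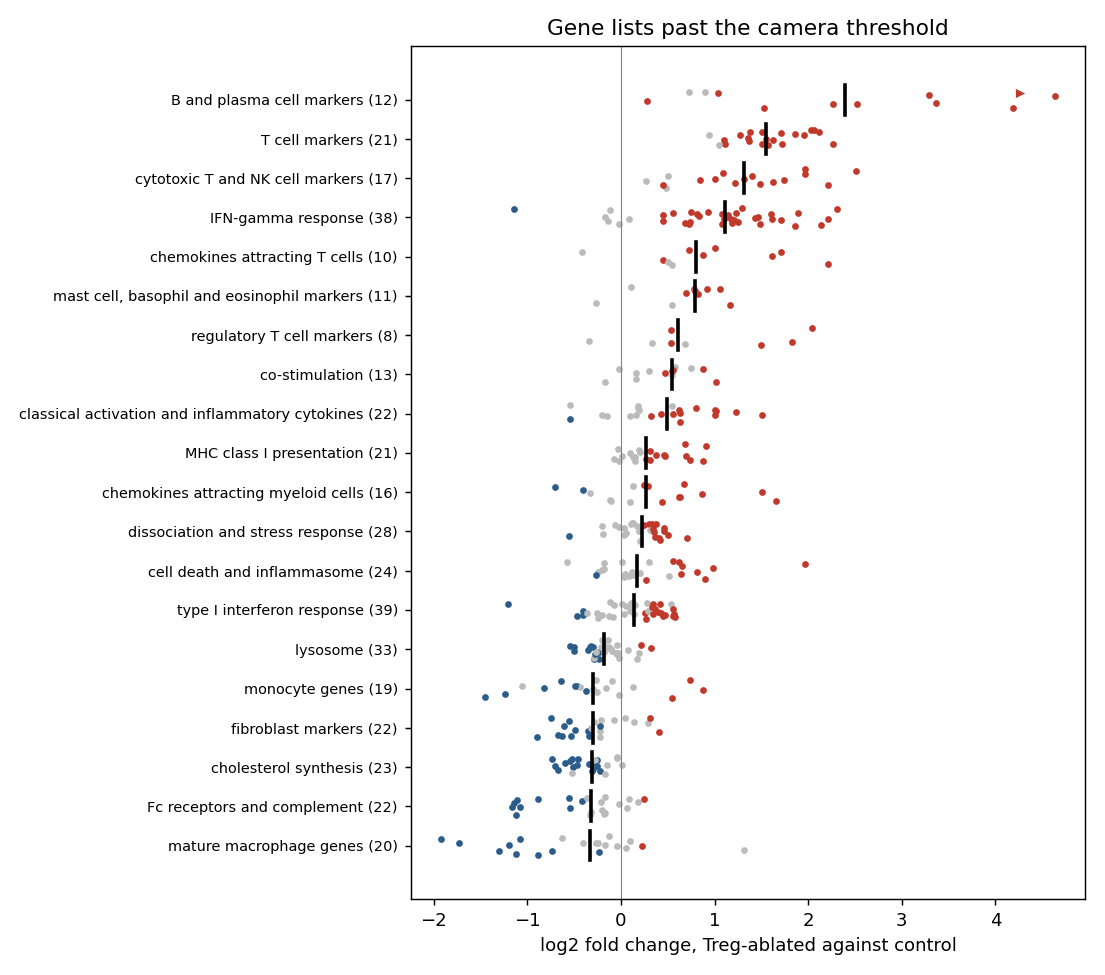
Log2 fold changes of the tested members of the 20 gene lists past the camera threshold with the preset correlation; the number tested is in brackets, red and blue points passed as higher and lower, grey points did not pass, and black bars are medians. The red triangle is Ms4a1, drawn at its lower bound because all controls had 0 counts. B cell, T cell and cytotoxic markers and IFN-γ response genes have the largest medians, between 1.11 and 2.40.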

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

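The GC correction was chosen after seeing the data; the other alternatives were planned. Of the counts, IFN-γ response genes higher stayed between 30 and 32 when each library was left out and between 23 and 32 under all 16 alternatives. For genes higher and genes lower after Treg cell ablation, the counts moved most under the test against a fold of 1.5, which gave 98 and 23, as it asks for larger changes. DESeq2 called 1214 higher and 1390 lower. Leaving out each library in turn gave 812 to 1687 higher and 554 to 1538 lower. The lowest values were both without control replicate 2. The number of libraries alone does not explain them, as 1687 were higher and 1441 lower without control replicate 1, and 1686 and 1538 without control replicate 3. Why control replicate 2 matters most was not tested. With the replicate number as a block, 1296 genes were higher and 1116 lower. The block ended the calls of Ifngr1 and Ly6c2 and of the type I interferon list and called the endothelial list lower. The numbers were not found to pair the libraries: the titles share only 2 numbers, and across genes the deviations from the group means correlated at −0.57 for replicates 1 and 0.01 for replicates 2. By the numbers in the file names the correlations were −0.01 for number 2 and −0.54 for number 3. The deviations of the 2 Treg-ablated libraries mirror each other, so these values are not independent, and the block was fitted only with the numbers of the titles. Libraries of different groups did vary together. On principal component 2 of log2 CPM (18.56% of the variance) Treg-ablated replicate 1 and control replicate 3 lay at 15.3 and 14.81. Treg-ablated replicate 2 and control replicate 1 lay at −14.67 and −14.45. What these libraries share was not tested, and no fit took it into account. With the GC offset 1624 were higher and 1222 lower, of which 1300 and 924 were also called in the main fit. Of the 3758 calls of the main fit, 59.18% were kept. With an estimated correlation, camera called 0 of the 14 lists higher and 0 of the 6 lists lower, with 5 and 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0719, whereas fry called 13 of the 14 and all 6, and 1 other list higher. Leaving out each library gave 13 to 14 lists higher and 5 to 8 lower. Of 54 named genes none turned in direction after passing in either fit, under any of the 16 alternatives. The test against a fold of 1.5 ended 25 of their calls, and no other alternative ended more than 4. Against a fold of 1.5, 0 members passed in several lists. Among these were the MHC class I, cholesterol synthesis, fibroblast, lysosome, mast cell and dissociation lists. Depth limits genes near the floor, such as Foxp3.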

Other observations

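The tests of fibroblast against macrophage levels and of lymphocyte list members below were chosen after the results were seen, as was the GC correction, while the bounds for the other tests were set before their values were known.

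Several gene groups not described above also differed. Of 11 mast cell, basophil and eosinophil markers 7 were higher after ablation and 4 did not pass (7 higher adjusted over the list alone; camera adjusted p = 0.000865, and adjusted p = 0.2043 with an estimated correlation). The count of 7 fell to 4 without Treg-ablated replicate 2 or control replicate 2. The mast cell protease genes Cpa3 and Mcpt4 rose 2.25-fold and 1.89-fold. Of 13 co-stimulation genes 5 were higher (5 adjusted over the list alone; camera adjusted p = 0.000865, and adjusted p = 0.1955 with an estimated correlation). This count was 3 without Treg-ablated replicate 1 or control replicate 3, 2 without control replicate 2 and 1 under DESeq2. Of 24 cell death and inflammasome genes 9 were higher and 1 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.016, and adjusted p = 0.1955 with an estimated correlation), but 4 and 0 without control replicate 2. The number lower in this list was 2 without Treg-ablated replicate 1 and 0 without Treg-ablated replicate 2 or control replicate 3. Type I interferon response genes were higher in 15 and lower in 4 of 39 (16 and 5 adjusted over the list alone), and in 7 and 2 without control replicate 2. Their median log2 fold change was 0.14, the camera adjusted p was 0.0262, and the adjusted p was 0.1955 with an estimated correlation; the call ended without Treg-ablated replicate 2 (adjusted p = 0.0618). Among genes chosen after their values were seen, the nuclear noncoding RNAs Malat1 and Kcnq1ot1 rose 1.93-fold and 1.98-fold, and Col14a1 and Pi16, which fibroblasts express, fell 2.86-fold and 2.38-fold.

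The other lists did not pass camera with either correlation (adjusted p with the preset one between 0.2653 and 0.9261), though some passed under an alternative. Members higher and lower were 6 and 3 of 19 for inhibitory ligands and cytokines, 11 and 6 of 32 for angiogenesis and matrix remodelling, 11 and 3 of 31 for hypoxia and glycolysis, 4 and 8 of 40 for the cell cycle, 4 and 4 of 18 for oxidative burst and nitric oxide, 4 and 3 of 19 for the unfolded protein response, 2 and 3 of 48 for oxidative phosphorylation and 8 and 1 of 51 for ribosomal proteins. Adjusted over the list alone, the numbers in the same order were 7 and 3, 11 and 6, 12 and 6, 7 and 10, 5 and 5, 4 and 5, 0 and 0, and 8 and 1. Without control replicate 2 they were 2 and 1, 7 and 5, 6 and 1, 0 and 2, 3 and 1, 1 and 1, 0 and 0, and 4 and 0. Oxidative phosphorylation genes passed camera as lower without Treg-ablated replicate 1 (adjusted p = 0.00075, 12 lower and 0 higher) and without control replicate 1 (adjusted p = 0.0432, 3 and 0), but 6 were higher and 0 lower without Treg-ablated replicate 2, and 2 higher and 1 lower without control replicate 3. Ribosomal protein genes passed as higher without Treg-ablated replicate 2 (adjusted p = 0.00221, 13 higher and 0 lower), whereas 3 were higher and 8 lower without Treg-ablated replicate 1, 5 and 1 without control replicate 1, and 8 and 2 without control replicate 3. The hypoxia list passed as higher with the GC offset (adjusted p = 0.0149) and the angiogenesis list under fry (adjusted p = 0.0268). Among the remaining moves of over 1.5 times, cell cycle genes higher and lower were 1 and 5 without Treg-ablated replicate 1, 3 and 5 without Treg-ablated replicate 2 and 2 and 7 without control replicate 1. Genes of the unfolded protein response were 2 and 5, 2 and 1, and 2 and 2 without Treg-ablated replicate 1, Treg-ablated replicate 2 and control replicate 3. Angiogenesis genes were 7 and 5 without Treg-ablated replicate 1, and inhibitory ligands 2 and 2 without Treg-ablated replicate 2. The median and the camera direction differed in sign for inhibitory ligands, neutrophil markers and the unfolded protein response. Vegfa, the endothelial growth factor gene, rose 1.49-fold and Myc, a growth-promoting transcription factor gene, 1.54-fold.

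In the remaining lists, of cell types and histone genes, members higher and lower were 4 and 2 of 18 for dendritic cell, 3 and 2 of 9 for neutrophil, 2 and 0 of 10 for epithelial, 0 and 1 of 10 for endothelial and 0 and 2 of 8 for erythroid and platelet markers, and 1 and 0 of 10 for histone genes. Adjusted over the list alone they were 4 and 2, 3 and 2, 2 and 0, 0 and 1, 0 and 2, and 0 and 0. The endothelial list passed camera as lower without control replicate 3 (adjusted p = 0.0441). Without control replicate 2 the numbers in the same order were 3 and 1, 1 and 1, 1 and 0, 0 and 0, 0 and 0, and 0 and 0. Without Treg-ablated replicate 1 they were 4 and 1, 0 and 2, 0 and 0, 0 and 1, 0 and 1, and 0 and 0, without Treg-ablated replicate 2 they were 4 and 2, 2 and 1, 1 and 0, 0 and 1, 0 and 1, and 1 and 0, and without control replicate 1 they were 4 and 2, 0 and 2, 1 and 0, 0 and 1, 0 and 0, and 0 and 0.

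The low level of mature macrophage genes in libraries labelled as sorted macrophages was weighed first. Reads shared with other annotated transcripts as the cause are argued against. The median share of 50-base words of the 23 mature macrophage genes found in any other gene was 0.0%, with a highest value of 19.9%. The measure counts exact matches to annotated transcripts only, and it gave 25.12% for Gapdh. Reads shared with inexact or unannotated copies are not covered. Missing exons are argued against too: the deposited exon lengths were, at the median, 100% of those in the reference annotation. A candidate explanation is that RNA of cells other than macrophages makes up most of the libraries, although the gate would remove such cells, but it was not tested: that the fibroblast list lay at least 5.88 times above the macrophage list per kilobase in every library restates the pattern and decides nothing. Whether such RNA, if present, came from fibroblasts or tumour cells, and whether through the sort or through a different sample than the labels say, stays open, and no macrophage library of known purity was analysed here.

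The rise of T, cytotoxic and B cell genes may come from more RNA of these cells in the Treg-ablated libraries, though the gate (CD11b, F4/80) would remove them. Among 50 members of the 3 lists tested 86.0% were higher and the other 7 did not pass, which restates the pattern and does not test that explanation. A GC trend is argued against, because it was small beside these changes. With the GC offset the median absolute log2 fold change of the members called higher went from 1.62 to 1.61. Of these members 97.67% were still called, which changes of that size make likely in any case. In the Treg-ablated libraries Igkc, Gzmb and Ighm had 32.45, 29.03 and 21.27 CPM, far below Fn1 (7850 to 11750 CPM over the 5 libraries). These values were however within the range of the macrophage gene Csf1r (20.52 to 52.54 CPM) and above that of Adgre1 (5.733 to 9.866 CPM). More RNA of T, NK and B cells, through Treg ablation, which the design names, or through a difference in the sort between groups, stays open and untested.

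The IFN-γ response and the many small changes were each set against the GC trend. For IFN-γ response genes, 100% of the 32 called higher were still called, which changes of that size make likely in any case. Their median absolute log2 fold change was 1.18 before and 1.10 after. The GC trend was small beside these changes, which argues against it as their cause. Of the 2822 calls of under 1.5-fold, 50.46% were still called in the same direction, and their median absolute log2 fold change went from 0.35 to 0.26. For these, a GC trend of the libraries and an effect of the ablation cannot be told apart, since the trend follows the groups: per 10 percentage points of GC it was −0.07 and −0.15 log2 units in the Treg-ablated libraries and 0.00, 0.11 and 0.10 in controls 1, 2 and 3. Which cells carried the IFN-γ response, and whether the ablation raised it, were not tested.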
